A study of Mus with 2 samples.

How the data were processed

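The material was 1 single-nucleus multiome library of mouse haematopoietic stem and progenitor cells, in which nuclear RNA and open chromatin (ATAC, which reads where a transposase can cut the DNA) are profiled in the same nuclei. Per the labels' protocols, the cells came from C57Bl/6 mice of 2 to 4 months, the marrow of 20 mice was pooled, and cells of the gate lineage-negative, Sca-1-positive, c-Kit-positive, CD150-positive, CD48-negative and CD45-positive were sorted. The nuclear RNA and the ATAC part are listed as 2 samples of this 1 library, so there was no replicate, no second condition and no comparison between conditions.

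The deposited tables used here were the list of features and the list of nucleus barcodes. Per the submitters' processing notes, they were made with Cell Ranger ARC 2.0.0 on the mouse build mm10. The settings of the peak caller, and whether peaks were called on all nuclei together, are not given in the sources used here. The list of features had 3 columns without a header, with 32285 genes (Ensembl identifier and symbol) and 139490 peaks (position only). A peak carried no height, no score and no number of nuclei, so each statement below is about where peaks were called and how many, and not about how open a site was. Counts per nucleus, and with them expression levels, clusters of nuclei and the depth of each nucleus, were not analysed here. Doublets were not examined here, and how they were treated before deposit is not given in the sources used here. The depth behind a peak is therefore unknown, and a site without a peak may be one that was open in too few nuclei to be called. The motif search planned before the data were examined needed the genome sequence, which was not used here, and was not run.

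Genes were placed with a RefSeq gene table of the assembly GRCm38.p6, the same primary assembly as mm10. Of the listed genes, 26255 matched a current symbol and 359 an older symbol, 5593 had no match and 78 carried a symbol that was listed more than once. After removal of genes on other contigs and of double matches, 26582 genes (82.3%) were placed, of which 20912 were protein-coding and 4715 were lncRNA genes. The gene table gave the outer bounds of each gene and no strand, exon or UTR. The design had assumed a transcription start site, so the planned fallback was used, in which both ends of a gene counted. A gene-end peak is a peak with its nearest edge within 1 kb of either end of a gene, and can therefore lie at the 3' end of a gene or belong to a neighbour or an overlapping or antisense gene. A distal peak lies over 1 kb from every gene end, and was assigned to the gene with the nearest end if that was within 100 kb. Start sites inside the outer bounds of a gene were not known, so a peak at one can count as distal. A gene without a gene-end peak may likewise have a peak at such an inner start site. The starts of peak positions were read as zero-based, as Cell Ranger ARC writes them, and are printed here counted from 1.

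Gene lists and 11 positions of known enhancers were fixed before the data were examined, and 278 of the 279 listed genes were placed (Mx1 was not among the listed genes). The lists covered long-term stem cell genes, a heptad of stem cell transcription factors, the proteins of the sorting gate, the ETS family, receptors for niche ligands, the blood lineages, endothelial and stromal cells, cell states, genes used by nearly all cells, and neuronal and hepatocyte genes as lists for other tissues. Each list was set beside 10000 random lists of the same size. For gene-end peaks these were matched gene by gene on the tenth of the number of other gene ends within 100 kb, and for distal peaks on the tenth of the territory, the stretch nearer to a gene's ends than to any other gene's, up to 100 kb on each side. Both were also matched on whether the symbol was provisional (Gm with digits, or ending in Rik). The result is a percentile, with ties counted at their mid-rank. A list is said to stand apart where its percentile was above 97.5 or below 2.5, a limit set before the percentiles were computed. Genes are not replicates, so a percentile describes this peak list and is not a p-value. For the distal peaks of a list the limit was applied to the mean over its genes, and the median is given beside it. The stem cell list was also set directly against each other list, with the percentile of the difference among 10000 relabellings of the genes of both lists, which were not matched on territory. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. To give the level expected from the number and width of peaks alone, the peaks were moved to random places on their own chromosome 100 times; such moves also reach gaps in the assembly.

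Genes named in the text followed a rule fixed before the data were examined. It took the 2 members of each list with the most distal peaks, the members without a gene-end peak where these were 5 or fewer and otherwise the first 2 of them, all members of the gate and heptad lists, the 20 genes without a provisional symbol with the most distal peaks, and the 5 widest peaks. Outside it, Msi2, Hlf, Hoxb5, Ctnnal1, Esam, Mycn, Notch2, Cxcr4, Flt1, Flt4, Kdr, Etv6 and Ets1 were chosen after their values were seen, as were the gene families. Ties in rank were all named. Some genes that the rule would name are not reported here.

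The scripts were tested on simulated data with the 26582 placed genes. For 400 simulated peaks and 1660 gene ends, 0 distances and 0 peak counts differed from a direct search. Of 200 simulated lists of 19 genes with no effect, 1.5% stood above and 1.5% below the limits for distal peaks, and 2.5% above and 1.5% below for gene-end peaks. Lists given 1.5-fold more distal peaks stood above the limit in 69.0% of cases, and lists given 2-fold more in 98.0%. The peaks in these runs lay at random places on their own chromosome, so the rates may differ for the real peaks and for lists of other sizes. Lists with no effect were random draws, as the reference lists are, so their rates check the calculation only. The alternatives tried were other distances from a gene end (500 bp and 2500 bp), the peak midpoint, the start of the gene interval alone, only peaks of at least the median width of 884 bp (the list has no score to be stricter on), placed genes without provisional symbols, other ways to assign distal peaks, and other backgrounds. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.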

Results

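The data describe the open chromatin of 1 sorted population, the CD150-positive CD48-negative fraction of lineage-negative Sca-1-positive c-Kit-positive marrow cells, which is enriched for long-term haematopoietic stem cells. The pool of 20 C57Bl/6 mice gave 5325 nuclei that passed the authors' filter, all with distinct barcodes of 16 bases and 1 suffix, that is, 1 library. In these nuclei 139490 peaks were listed beside 32285 genes. With 1 library no value has a replicate error. The comparisons possible in this design were between groups of loci, and asked which genes had regulatory sites called open around them in these cells.

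Peaks were of nearly uniform width, with a median of 884 bp (quartiles 837 and 907 bp, up to 1971 bp), and covered 120 Mb in all. On the numbered chromosomes, X and Y there were 139443 peaks. Chromosome 11 had 80.8 peaks per Mb and chromosome 19 had 74.4, against 45.5 on chromosome 3 and 45.9 on chromosome 14. The X chromosome had 20.6 peaks per Mb, below the range of 45.5 to 80.8 over the 19 autosomes, and 3.53 peaks per placed gene, where the autosomes ranged from 3.53 (chromosome 7) to 6.74 (chromosome 18). The 5 widest peaks lay on chromosome 18 (11973625 to 11975595, 4.52 kb from an end of Tmem241), chromosome 10 (94353761 to 94355725, 42.1 kb from Tmcc3), chromosome 5 (111892748 to 111894617, 85.4 kb from Gm36535), chromosome 19 (29658475 to 29660328, 10.1 kb from Ermp1) and chromosome 15 (60852950 to 60854790, 21.6 kb from 9930014A18Rik).

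Open sites were concentrated at gene ends, although most of them were distal. Of the 139443 peaks, 23016 (16.5%, interval 16.3 to 16.7%) lay within 1 kb of a gene end, 3.12 times the mean of 5.29% for relocated peaks (range 5.17 to 5.45% over 100 relocations). The other 116427 peaks (83.5%) were distal, with a median distance of 16.4 kb to the nearest gene end, and 91.1% of them lay within 100 kb of one. Peak midpoints fell inside a placed gene for 59.7% of all peaks, against 44.1% of relocated peaks (range 43.7 to 44.4%). Of the 26582 placed genes, 18309 (68.9%, interval 68.3 to 69.4%) had a gene-end peak, against a mean of 26.1% with relocated peaks. The share was 73.9% (interval 73.3 to 74.5%) for protein-coding genes and 55.5% (interval 54.1 to 57.0%) for lncRNA genes. A peak at only 1 of the ends was present for 48.8% of genes and at both ends for 20.1%. The share of genes depended on the definition, and was 64.7% within 500 bp and 40.5% when only peaks of at least the median width were kept.

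Loci of stem cell regulators were surrounded by more distal peaks than loci with the same room for them. The 19 long-term stem cell genes had a mean of 12.7 ± 11.2 distal peaks (SD over genes, n = 19) and a median of 10, against a mean of 6.53 in random lists matched on territory (central 95% of lists 3.89 to 9.63). Their mean stood at the 99.99 percentile and their median at the 99.9 percentile. Mllt3, a chromatin reader linked to stem cell maintenance, had 41 distal peaks and Mecom, a zinc finger transcription factor needed by long-term stem cells, had 30. Msi2 (28) and Hlf (18), named after their values were seen, were also above the mean of the list. Of the members chosen after their values were seen, Hoxb5 had 0 distal peaks, since the ends of neighbouring Hox genes lie nearer, although 18 distal peaks lay within 50 kb of it, and Ctnnal1, Esam and Mycn had 2 each.

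The heptad of transcription factors that bind together at stem cell enhancers had the highest mean of the lists. Its 7 genes had a mean of 20.4 ± 16.5 distal peaks (SD over genes, n = 7), above all 10000 matched lists, whose mean was 6.73. Runx1 (chromosome 16, 92601466 to 92826074) had 41 distal peaks, Fli1 (chromosome 9, 32422204 to 32543432) had 35, Erg (chromosome 16, 95359169 to 95586600) had 34 and Lmo2 (chromosome 2, 103957903 to 103981878) had 21. Gata2 (chromosome 6, 88193891 to 88207032), Tal1 (chromosome 4, 115056426 to 115071755) and Lyl1 (chromosome 8, 84701423 to 84704716) had 4 each. With peaks assigned to the nearest gene end, the heptad mean was therefore carried by 4 loci. Gata2, Tal1 and Lyl1 had small territories, of 40.2, 30.4 and 11.6 kb. Within 50 kb of them lay 14, 13 and 14 distal peaks, against 29 for Runx1, 39 for Fli1, 20 for Erg and 17 for Lmo2. The difference of the heptad median (21) from that of the stem cell list did not stand apart (10.1 percentile). All 7 had a gene-end peak, and 6 of them at both ends, Fli1 being the exception.

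**Figure D1:**
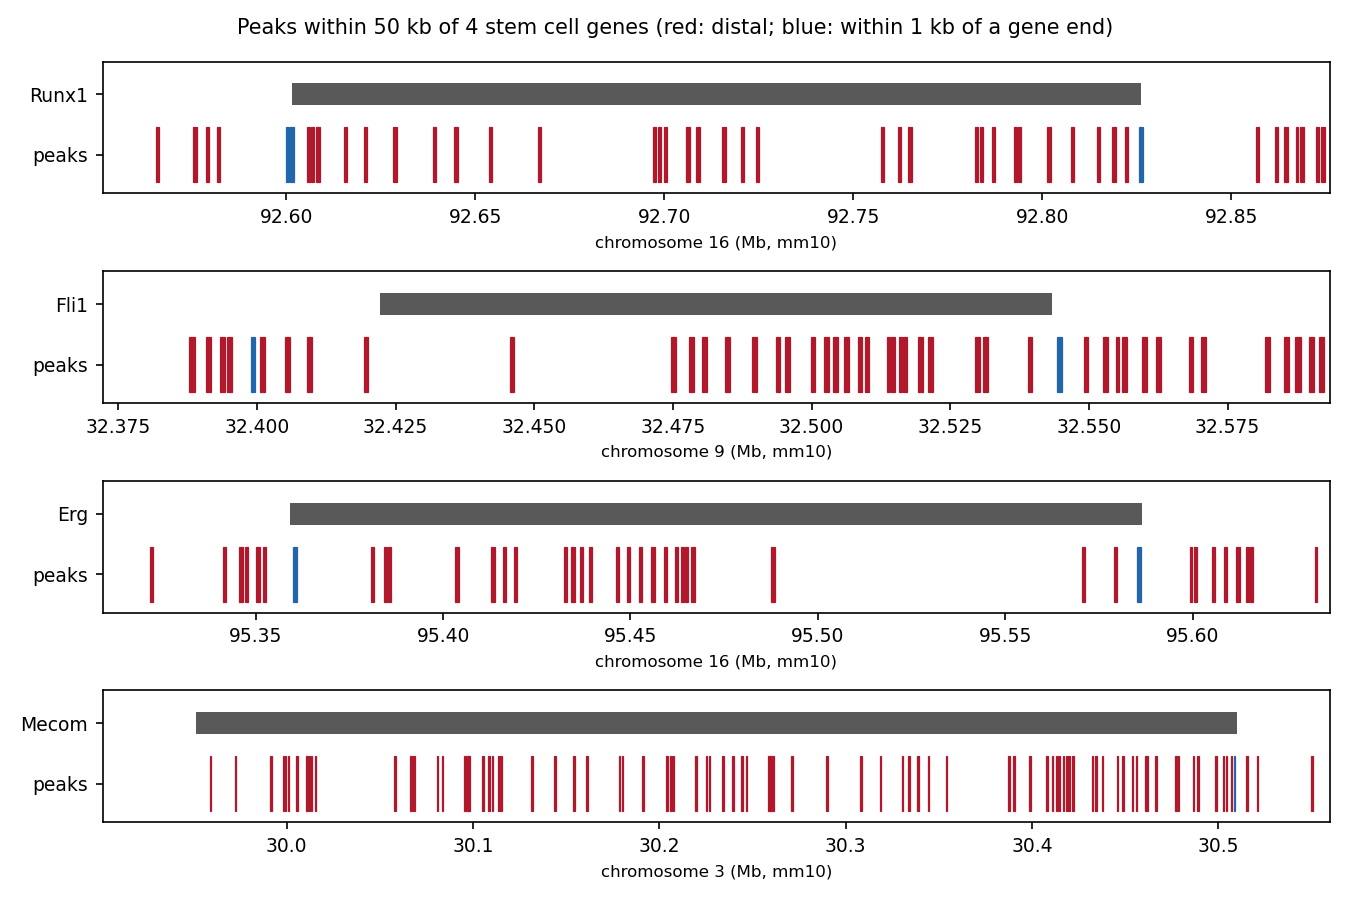
Peaks (boxes to scale, red for distal and blue for within 1 kb of any gene end) and the gene interval (grey) of Runx1, Fli1, Erg and Mecom with 50 kb on either side, against chromosome position in Mb (mm10). The map holds 45 peaks at Runx1, 46 at Fli1, 39 at Erg and 87 at Mecom, where 30 were assigned as distal peaks because much of the gene lies over 100 kb from its ends or nearer to another gene.

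Receptors through which marrow cells sense their niche showed the same excess. The 23 receptor genes had a mean of 13.8 ± 9.37 distal peaks (SD over genes, n = 23), above all 10000 matched lists (mean 7.47), and a median of 11. Kit, the receptor of stem cell factor, had 33 distal peaks and Igf1r, the insulin-like growth factor receptor, had 31. Notch2 (30), Cxcr4 (24), Flt1 (20) and Kdr (17), named after their values were seen, also lay above the mean of matched lists. All 23 had a gene-end peak, Kdr, Flt1 and Flt4 for vascular endothelial growth factors included.

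The ETS family, of which Fli1 and Erg are members, had a mean of 9.88 ± 9.75 distal peaks (SD over genes, n = 26) and stood at the 99.97 percentile. Fli1 and Erg had the most. Without them, which also removes the overlap with the heptad, the list stood at the 99.3 percentile. Etv6 (25) and Ets1 (21) came next, chosen after their values were seen. A gene-end peak was present at 24 of the 26 members (92.3%, interval 74.9 to 99.1%). The exceptions were Elf5 and Spdef.

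All 5 genes of the sorting gate had a gene-end peak, including Cd48, whose protein the gate excluded. Kit had 33 distal peaks, Ptprc (CD45) 18, Slamf1 (CD150) 8, Ly6a (Sca-1) 7 and Cd48 6. The list mean of 14.4 stood at the 98.0 percentile, while its median of 8 stood at the 80.1 percentile, and without Kit and Ptprc the mean stood at the 83.7 percentile.

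Blood lineage genes had fewer distal peaks than the stem cell genes, but did not stand below lists matched on territory. The 14 megakaryocyte genes had a mean of 5.57 ± 8.36 distal peaks (SD over genes, n = 14; 98.1 percentile) and a median of 1.5 (78.4 percentile). The excess in the mean came from Vwf (24), the platelet adhesion protein, and Itgb3 (23), a subunit of the platelet fibrinogen receptor, and was at the 67.6 percentile without them. Means were 3.94 for the 16 erythroid genes (61.4 percentile), 2.82 for the 17 neutrophil and monocyte genes (90.4 percentile), 3.93 for the 14 B lymphoid genes (64.7 percentile) and 4.44 for the 18 T and natural killer genes (85.5 percentile), none of which stood apart. The members with the most distal peaks were Ank1 (10) among erythroid genes, Irf8 (14) and Ly6c2 (5) among neutrophil and monocyte genes, Ebf1 (14) and Dntt (11) among B lymphoid genes, and Cd2 (15) and Klrb1c (12) among T and natural killer genes.

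The median number of distal peaks was 10 for the stem cell list, against 3 for the erythroid (difference at the 99.8 percentile of relabelled lists), 2 for the neutrophil and monocyte (99.9 percentile), 2 for the B lymphoid (99.3 percentile), 3 for the T and natural killer (98.2 percentile) and 1.5 for the megakaryocyte list (97.47 percentile, inside the limit). These relabellings take no account of territory, and the median territory was 79.5 kb for stem cell genes but 46.7 kb for erythroid, 17.7 kb for neutrophil and monocyte, 28.8 kb for B lymphoid, 32.5 kb for T and natural killer and 21.7 kb for megakaryocyte genes. Per 100 kb of territory the median was 12.4 distal peaks at stem cell genes, 10.8 at megakaryocyte, 9.84 at neutrophil and monocyte, 8.22 at erythroid, 7.94 at T and natural killer and 6.08 at B lymphoid genes. On that scale none of these differences stood apart, with percentiles of 65.3 (megakaryocyte), 82.9 (neutrophil and monocyte), 91.9 (erythroid), 89.1 (T and natural killer) and 95.7 (B lymphoid). The differences from cell cycle (97.4 percentile), neuronal (95.8), nearly-all-cells (72.8) and interferon genes (70.1) did not stand apart on it either, and of the other-tissue lists only hepatocyte genes, with 1.60 per 100 kb, differed (99.99 percentile).

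Genes of quiescence and the immediate early response had more distal peaks than matched lists, with a mean of 7.44 ± 8.56 (SD over genes, n = 16; 99.7 percentile), led by the forkhead factors Foxo1 and Foxo3 with 27 each. The 16 cell cycle genes did not stand apart (mean 2.94, 58.2 percentile), with Rrm2 (11) and Cdk1 (7) the highest. The 13 interferon response genes (mean 2.92, 99.8 percentile) and the 20 genes used by nearly all cells (mean 3.30, 99.1 percentile) stood apart by their means but not by their medians (63.1 and 95 percentiles). When the random lists were matched on neither territory nor provisional symbol, both means lay below the middle of these lists (24.8 and 30.9 percentiles). Ifi47 (11) and Irf1 and Rsad2 (6 each) led the interferon list, and Ywhaz (17) and Hprt (9) the genes used by nearly all cells. Endothelial (mean 5.15, 90.7 percentile; Pecam1 and Egfl7 with 14 each) and stromal genes (mean 8.33, 78.5 percentile; Runx2 with 20, Pdgfra with 14) did not stand apart. Neuronal genes had a mean of 4.93 (14.5 percentile; Rbfox3 and Gad1 with 14 each) and hepatocyte genes 1.67 (2.61 percentile; G6pc with 5 and Cps1, Tat and Pck1 with 4 each).

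**Figure D2:**
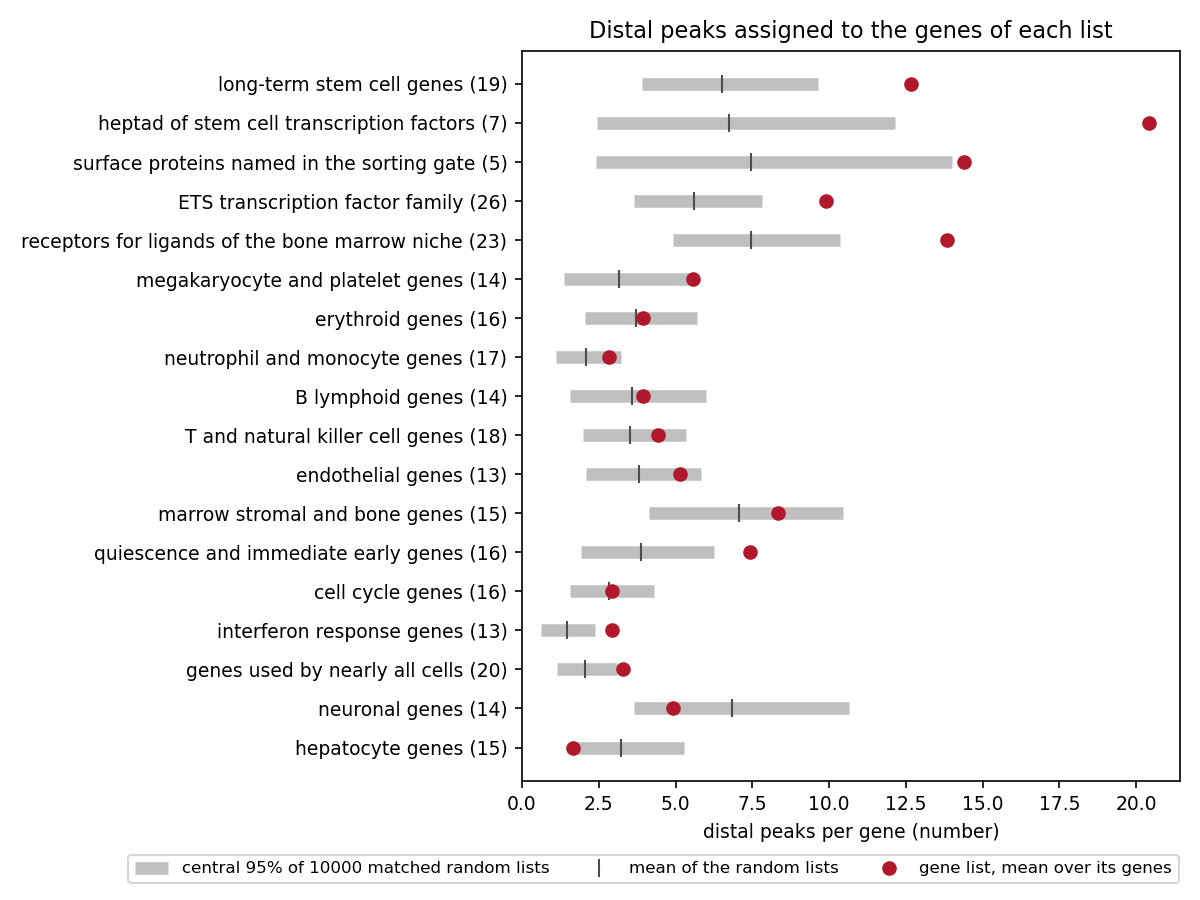
Mean number of distal peaks per gene (x axis) for each list (y axis, number of placed genes in brackets), with the list mean as a red point, the mean of 10000 matched random lists as a tick and the central 95% of these as a grey bar. The stem cell list (12.7), the heptad (20.4) and the receptor list (13.8) lie to the right of their bars, and the B lymphoid (3.93) and erythroid (3.94) lists lie within them.

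Of the 20 genes with the most distal peaks among placed genes without a provisional symbol, Mllt3 and Runx1 were members of the fixed lists. Med13l, a subunit of the mediator kinase module, had 54 distal peaks, Zmiz1 51, the corepressor Bcor 49 and Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, 48. They were followed by Plcl2 (47), Mbnl1 (46), Arid1b, Prex1 and Smad3 (45 each), Sept9 (44), Elmo1 (43), Itga9 (42), Mllt3 and Runx1 (41 each), Cdk19, Gnaq and the lncRNA gene Lncpint (40 each), Tcf7l2 (39), and Cmip and Maml3 (38 each). All 20 had a gene-end peak. This ranking is not corrected for territory, which ran from 193 kb for Lncpint to 393 kb for Med13l, where the median over all placed genes was 42.6 kb.

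Over all lists, 9 percentiles for gene-end peaks and 9 for the mean of distal peaks, of 36 in all, lay outside the central range, where 1.8 are expected by chance if every list could reach both limits. For gene-end peaks the heptad and gate lists could not, since even with a peak at every member they stood at the 93.0 and 88.2 percentiles. Lists that share genes are also not independent. Gene-end peaks were present at 19 of 19 stem cell genes (100%, interval 82.4 to 100%), where matched random lists had a mean of 75% (99.8 percentile), and at all members of the receptor, quiescence, cell cycle and interferon lists (99.96, 99.5, 99.5 and 99.2 percentiles). Genes used by nearly all cells had one at 19 of 20, with Ywhaz as the exception (98.5 percentile), erythroid genes at 15 of 16, with Gata1 as the exception (97.7 percentile), and neuronal genes at 13 of 14, with Dcx as the exception (95.2 percentile). Lower shares were found for megakaryocyte genes (11 of 14, without Gp6, Ppbp and Mpig6b), endothelial genes (10 of 13, without Cdh5, Stab2 and Egfl7), stromal genes (13 of 15, without Prrx1 and Adipoq), T and natural killer genes (13 of 18, without Cd8a, Gata3, Zap70, Ncr1 and Gzma), neutrophil and monocyte genes (11 of 17, with Ms4a3 and Cebpe among the 6 without) and B lymphoid genes (8 of 14, with Pax5 and Ms4a1 among the 6 without). Of these, none fell below the 2.5 percentile within 1 kb. The B lymphoid list did within 500 bp (1.62 percentile), but within 2500 bp it stood at the 67.0 percentile, so its direction depended on the distance. The hepatocyte list fell below the 2.5 percentile within 1 kb, with 5 of 15 genes (33.3%, interval 11.8 to 61.6%, 0.045 percentile), Apoc3 and Ttr being among the 10 without. The stem cell share exceeded that of the B lymphoid list by 42.9 percentage points (99.9 percentile of relabelled lists), of the neutrophil and monocyte list by 35.3 (99.7 percentile) and of the T and natural killer list by 27.8 (99.0 percentile). Its differences from the megakaryocyte list (21.4 points, 96.75 percentile) and the erythroid list (6.25 points, 76.5 percentile) did not stand apart. The 3 calls did not hold for the wider peaks alone, where the percentiles of the differences were 81.7, 62.6 and 55.5, and within 500 bp of a gene end the stem cell list stood at the 88.7 percentile. With the wider peaks alone the receptor (82.3), quiescence (93.6), cell cycle (92.3), nearly-all-cells (90.8), erythroid (84.3), ETS (62.9) and hepatocyte lists (3.40) did not stand apart either, and with a peak required at both ends the interferon list stood at the 67.0 percentile.

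**Figure D3:**
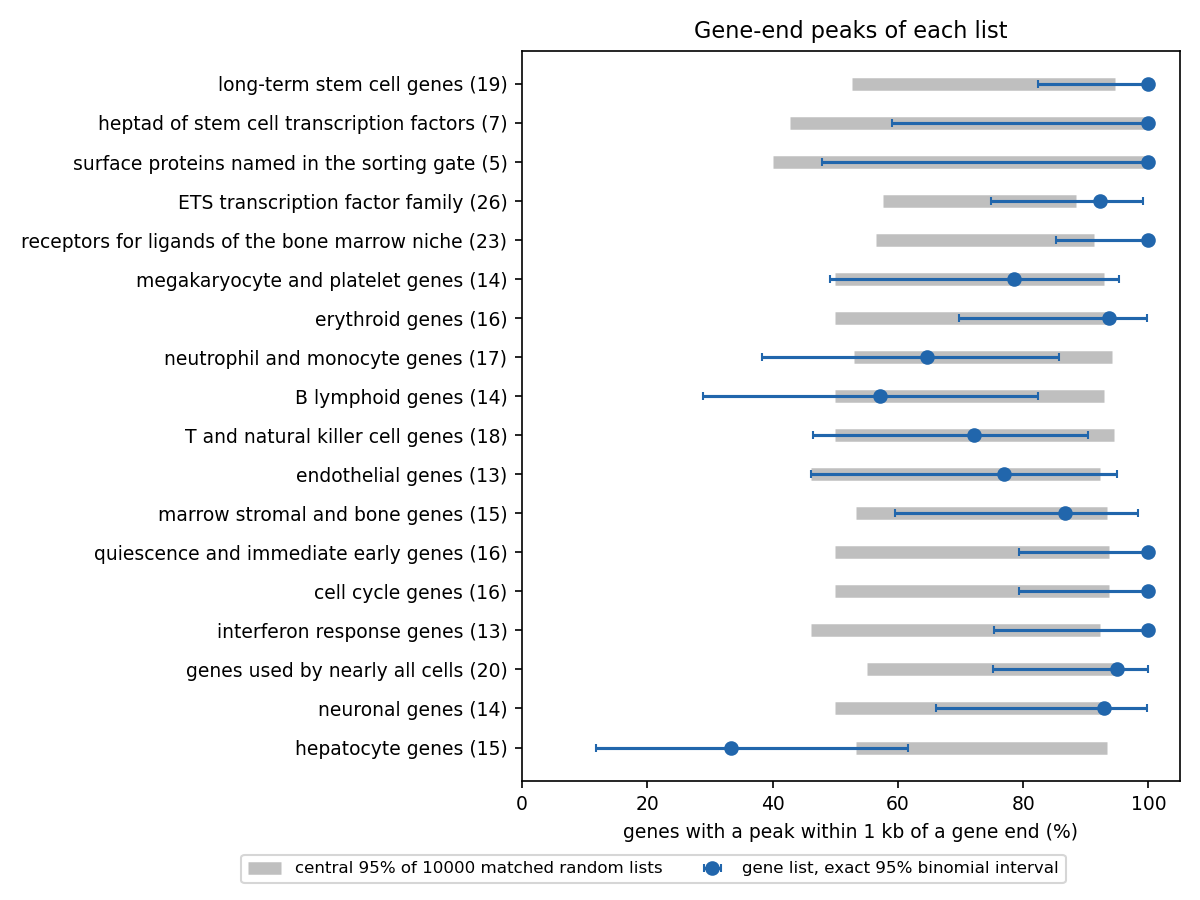
Percent of the genes of each list (y axis, number of placed genes in brackets) with a peak within 1 kb of a gene end (x axis), as blue points with exact 95% binomial intervals, and the central 95% of 10000 matched random lists as grey bars. The hepatocyte list, at 33.3%, lies left of its bar, and the B lymphoid list, at 57.1%, lies within it.

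Positions of published blood enhancers were examined as a check on the regulatory map. The positions were given by their distance from the gene's start. In at least 1 orientation of the gene, all 11 had a peak within 2 kb (100%, interval 71.5 to 100%). As the strand was not given, either orientation was accepted. Treated the same way, the 20886 placed genes without a provisional symbol gave 6.33 expected hits, and those with a gene-end peak gave 7.45. Of the hits, 4 held in both orientations (Tal1 +19 kb, Gata2 +9.5 kb, Gata2 -77 kb and Cebpa +37 kb) and 7 in only 1 of them. Each of these 7 may be a miss in the gene's true orientation, so the 100% can overstate the share. A hit at Hhex +1 kb says little, since this position had one for 100% of the genes with a gene-end peak. The published distances are rounded and are counted from different landmarks. In at least 1 orientation, peaks covered the expected position for Gata2 +9.5 kb (chromosome 6, 88202815 to 88203725, inside the gene), Gata2 -77 kb (88116332 to 88117196, outside it), Fli1 +12 kb (chromosome 9, 32530984 to 32531749, inside the gene), Tal1 +19 kb (chromosome 4, 115075266 to 115076169, outside the gene), Cebpa +37 kb (chromosome 7, 35156209 to 35157119, outside the gene) and Hhex +1 kb (chromosome 19, 37435299 to 37436203, inside the gene). In the nearer and the farther orientation, the nearest peak was 0.014 and 3.17 kb away for Tal1 +40 kb, 0.663 and 2.07 kb for Gata2 -3 kb, 0.863 and 3.01 kb for Runx1 +23 kb, 1.61 and 2.06 kb for Spi1 -14 kb and 1.91 and 13.1 kb for Erg +85 kb. In the farther orientation it was 11.3 kb away for Fli1 +12 kb and 2.47 kb for Hhex +1 kb.

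All 4 Hox clusters, which hold the homeobox genes of body patterning, carried peaks along their length. The Hoxb cluster (chromosome 11, 96194316 to 96368254) held 48 of the 120 peaks (40%, interval 31.2 to 49.3%) in 174 kb, the Hoxc cluster (chromosome 15, 102921131 to 103036856) 29 in 116 kb, the Hoxa cluster (chromosome 6, 52155367 to 52260880) 23 in 106 kb and the Hoxd cluster (chromosome 2, 74668225 to 74765142) 20 in 96.9 kb. Per kb the densities were close, at 0.276 for Hoxb, 0.251 for Hoxc, 0.218 for Hoxa and 0.206 for Hoxd, and peaks covered 22.3, 20.2, 18.3 and 17.7% of the clusters. A gene-end peak was present at 10 of 10 Hoxb, 9 of 9 Hoxc, 10 of 11 Hoxa and 7 of 9 Hoxd genes. With the wider peaks alone the Hoxb share was 31.1%, and the clusters were not tested against each other.

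**Figure D4:**
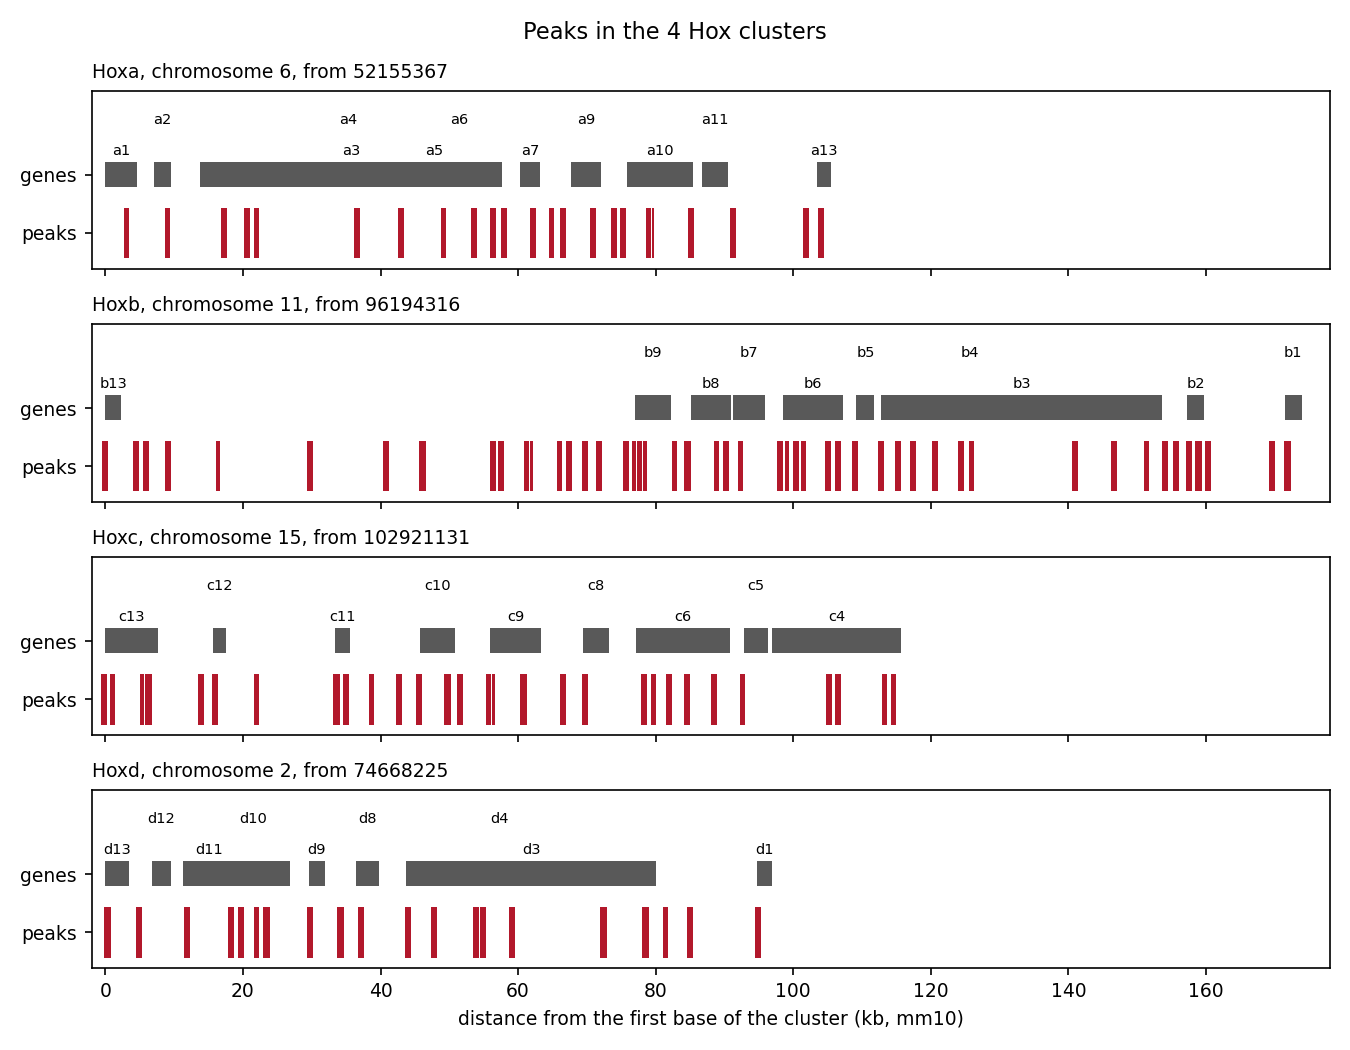
Peaks (red boxes) and gene intervals (grey boxes, labelled by cluster letter and number) of the 4 Hox clusters against the distance in kb from the first base of each cluster (mm10). Peaks are spread along all 4 clusters, with 48 in the longest, Hoxb, and 20 in the shortest, Hoxd.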

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

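The test of peaks away from the Y-linked genes was chosen only after its result was seen, and the tests of the Y-linked genes and of Xist were set before. No list gene lay on an unplaced contig or on the Y chromosome. The 123 placed genes of the Y chromosome were, however, among the genes from which random lists were drawn. The unplaced contigs and the Y chromosome each held more peaks than the limit of 3 that a count of 0 allows. There were 47 peaks on 5 unplaced contigs (26, 13, 6, 1 and 1 peaks), where no gene was placed, so these peaks have no assigned gene.

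The Y chromosome held 27 peaks, of which 16 lay between 90.7 and 90.8 Mb at its far end, around the region that pairs with the X, and 11 lay in the first 5 Mb. All 4 of the broadly used Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had a gene-end peak, and Xist, the RNA that silences 1 X chromosome in female cells, had 4 peaks within 1 kb of its ends. Male mice in the pool may account for the first and female mice in the pool for the second, and a pool of both sexes remains a hypothesis, since the labels give no sex. Reads shared with X copies of the Y-linked genes stay open as a source: 7 of the peaks in the first 5 Mb lay over 1 kb from the ends of the 4 genes, but repeated sequence was not examined. Peaks at Xist in male cells stay open too, since a peak carries no level.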

How the results depend on the processing

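The tests chosen only after the data were examined were a peak at both gene ends, the background of genes with a gene-end peak, lists without their 2 leading members, differences per 100 kb of territory, and enhancer orientation read from the peaks. The last covered 2 positions and says little, since the hit at Hhex follows from the peak that orients it. The distal-peak means of the stem cell, heptad, receptor, ETS and quiescence lists stood apart under every alternative run, the lowest percentiles being 98.1 (stem cell), 99.9 (heptad), 99.95 (receptor), 99.2 (ETS) and 97.7 (quiescence). Of all alternative values 266 kept their call or stayed within their interval, 57 lost a call, 2 lost one and moved to the other side of the middle of the random lists, 11 gained one and 13 shares moved. Among the 266 are the gene-end percentiles of the lists without provisional symbols, which could not change. No list gene has such a symbol, and the random lists were already matched on it. There were 32 values that stood apart in neither case and crossed the 50 percentile. Values below are percentiles unless given as a share. For distal peaks, a background matched on neither territory nor provisional symbol moved the interferon (24.8) and nearly-all-cells lists (30.9) to the other side of the middle, where neither stood apart. It lost the megakaryocyte list (86.2) and gained the stromal (99.5) and hepatocyte lists (1.86), and the parts of the 2 matchings in this were not separated. The median territory was 15.6, 23.1, 21.7, 137 and 39.8 kb for these lists in this order, and 42.6 kb over all placed genes. Counting all distal peaks within 50 kb lost the gate list (92.8) and the difference from interferon genes (84.3). Assignment to genes without provisional symbols lost the gate (96.2) and megakaryocyte lists (96.9) and gained the hepatocyte list (1.37), and a limit of 2500 bp lost the megakaryocyte list (96.5). Against genes with a gene-end peak the gate (95.8) and nearly-all-cells lists (85.7) were lost. Without the 2 leading members the gate (83.7), megakaryocyte (67.6), interferon (92.6) and nearly-all-cells lists (92.4) were lost and the hepatocyte list gained (1.73). Per 100 kb of territory, the differences of the stem cell list from the erythroid (91.9), neutrophil and monocyte (82.9), B lymphoid (95.7), T and natural killer (89.1), cell cycle (97.4), interferon (70.1), nearly-all-cells (72.8) and neuronal lists (95.8) were lost. For gene-end peaks, a distance of 500 bp lost the stem cell (88.7), ETS (93.8) and nearly-all-cells lists (97.2), gained the B lymphoid list (1.62), and gave shares of 64.7% of genes and 13.3% of peaks. A distance of 2500 bp lost the erythroid (93.8) and nearly-all-cells lists (95.2), gained the stromal list (98.4), and gave 75% of genes and 24.2% of peaks. The peak midpoint lost the stem cell (95.9), ETS (92.8) and nearly-all-cells lists (96.7) and gave 65.5% of genes and 13.9% of peaks. The start of the gene interval alone, which drops 1 of the ends of each gene, lost the stem cell (82.2), ETS (85.4), erythroid (85.1), quiescence (87.7), cell cycle (56.8), interferon (97.1) and nearly-all-cells lists (91.5), gained the heptad (97.7), and gave 44.7% of genes and 9.71% of peaks. A peak at both ends lost the stem cell (79.0), ETS (65.6), erythroid (53.9), quiescence (93.9), cell cycle (83.1), interferon (67.0) and nearly-all-cells lists (88.1) and gained the heptad (100). The heptad could not stand apart in the main setting, where all 7 of its genes had a gene-end peak and this highest possible share stood at 93.0. Genes without provisional symbols had a share of 74.2%, and 14.4% of peaks lay at their ends. With only the peaks of at least the median width, the gene-end calls of the stem cell (78.7), ETS (62.9), receptor (82.3), erythroid (84.3), quiescence (93.6), cell cycle (92.3), nearly-all-cells (90.8) and hepatocyte lists (3.40) were lost and the neuronal list gained (99.7). The differences in gene-end share from the neutrophil and monocyte (62.6), B lymphoid (81.7), T and natural killer (55.5) and hepatocyte lists (96.8) were lost, as were the distal peaks of the interferon (80.4) and nearly-all-cells lists (90.1) and the distal difference from the neuronal list (97.3), while the hepatocyte distal peaks (2.09) and the distal difference from the megakaryocyte list (98.1) were gained. With these peaks the shares were 40.5% of genes and 14.9% of peaks, and 31.1% of Hox peaks lay in Hoxb. The cause of these changes was not tested. The alternatives for motifs were not run, and joining peaks that touch left all 139490 as they were. The lack of a depth per peak limits every count of sites without one.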

Other observations

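The gene families and variable segments, the comparison with open genes and the leave-out of the 2 leading members were chosen after the data were examined, the last of these before its value was seen. Families used by all cells nearly always had a gene-end peak: 47 of 47 respiratory complex genes (Nduf), 77 of 78 mitochondrial ribosomal protein genes, 46 of 48 proteasome genes (Psm) and 76 of 80 ribosomal protein genes. Zinc finger genes (Zfp) had one at 329 of 387 (85%, interval 81.1 to 88.4%), integrin genes at 22 of 24 and interleukin receptor genes at 35 of 40. Families of sensory receptors rarely did, with 45 of 1098 olfactory receptor genes (4.10%, interval 3.0 to 5.45%), 4 of 329 vomeronasal receptor genes (1.22%, interval 0.332 to 3.08%) and 1 of 35 taste receptor genes (2.86%, interval 0.0723 to 14.9%). Shares in between were found for beta-defensin genes (5 of 42, 11.9%), keratin genes (24 of 109, 22.0%, interval 14.6 to 31.0%) and cytochrome P450 genes (41 of 99, 41.4%, interval 31.6 to 51.8%). Clustered protocadherin genes had one at 39 of 55 (70.9%, interval 57.1 to 82.4%), although their distal peaks were few, at 1.23 per 100 kb of territory against 8.80 for integrin genes. In a cluster 1 peak can count as the gene-end peak of several members. Whether it did was not examined, and the interval treats the members as separate.

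The variable segments of the antigen receptors, which are rearranged only in lymphocytes, differed by locus. A peak lay within 1 kb of 61 of 120 Ighv segments (50.8%, interval 41.6 to 60.1%), 42 of 112 Trav segments (37.5%, interval 28.5 to 47.1%) and 14 of 22 Trbv segments (63.6%, interval 40.7 to 82.8%), but of 2 of 101 Igkv segments (1.98%, interval 0.241 to 6.97%). Over the whole span of segments the density was 4.89 peaks per 100 kb at Ighv (chromosome 12), 5.80 at Trav (chromosome 14) and 7.20 at Trbv (chromosome 6), and 0.286 at Igkv (chromosome 6). The whole chromosomes 12, 14 and 6 had 49.7, 45.9 and 54.9 peaks per Mb. Ighv was thus near the level of its chromosome, Trav and Trbv were somewhat above theirs, and Igkv was far below. These differences were not tested. Segments of a locus resemble each other, and the placement of reads among them was not examined.

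The excess of distal peaks at long-term stem cell genes was weighed against 4 technical explanations. Long or isolated genes take more peaks, but the list stayed at the 99.99 percentile among lists matched on territory. Assignment to the nearest gene did not account for it, since the percentile was 99.9 when all distal peaks within 50 kb were counted, nor did a few loci, since it was 99.5 without Mllt3 and Mecom. Against matched genes that had a gene-end peak themselves, the percentile was 99.96, so the presence of such a peak alone did not account for it. A peak carries no level, so genes could not be matched on how open or active they were, and that explanation stays open. Nor could genes be matched on start sites inside their bounds, whose peaks can count as distal, so their part was not tested. Per 100 kb of territory, however, the list did not stand apart from megakaryocyte (65.3 percentile), interferon (70.1), nearly-all-cells (72.8) or neutrophil and monocyte genes (82.9), so the excess is over matched genes in general and is not shown to be particular to stem cell genes. A candidate explanation is that regulatory sites of stem cell genes are in use in these cells; it remains an untested hypothesis, since sequence content was not examined and no second cell type was compared.

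Gene-end peaks at genes of other lineages are hard to read from a list without levels. Of the 79 genes of the 5 blood lineage lists, 58 had one (73.4%, interval 62.3 to 82.7%). Among all placed genes without a provisional symbol the share was 74.2%, so the pooled lists had no excess over genes in general. If gene ends that are open in any tissue were the source, the neuronal and hepatocyte lists should have about as many, and they had 62.1% (18 of 29, interval 42.3 to 79.3%), with the neuronal list at 13 of 14 and the hepatocyte list at 5 of 15. That lies just under the lower bound for the blood lineages, by less than its own counting error, and the 2 lists behind it go opposite ways, so the outcome depends on which of them is used. Openness in any tissue and lineage genes held open in stem cells cannot be told apart here, and a small number of other cells in the sort was not tested.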
